A study of Arabidopsis thaliana with 12 samples.

How the data were processed

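RNA-seq was read in 12 libraries from 14-day-old Arabidopsis thaliana plants, 3 each of the wild type Col-0, the dominant-negative AHL mutant sob3-6, the AHL overexpressor SOB3-D and the triple loss-of-function mutant pif4 pif5 pif7. AHL proteins are AT-hook DNA-binding proteins, and PIFs are phytochrome-interacting bHLH transcription factors. Per the labels, plants grew at 22 °C in 16 h light and 8 h dark, under white fluorescent light of about 35 to 55 µmol per square metre per second, on medium without sucrose. The shoot above a cut through the hypocotyl was harvested at ZT4, 4 h after lights on. RNA was purified on columns with DNase digestion, and libraries were made with a stranded mRNA kit, per the labels' protocols. Whether the counting used strand is not given in the sources used here, so a gene and an antisense or overlapping partner may share reads.

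Per the submitters' processing notes, bcl2fastq and Bowtie 1.2.1 were used, with the TAIR10 genome. Each deposited file gives a signal per transcript, in parts-per-million of mapped tags (ppm) per the labels, for 32950 transcripts of 25089 loci. The deposited signal values of a library sum to between 1599902 and 1626178, more than a parts-per-million scale allows. Taking only the most abundant transcript of each locus, they sum to between 1063973 and 1068838. From this it was inferred, not stated by the authors, that a read was counted in every transcript it matched. The unit was therefore treated as a scaled read signal rather than as a share of the library, while the test fixed for ppm values was kept. In each library the values were whole multiples of the value of 1 read, 100% of them within 0.01 reads and with a largest deviation of 7.9e-05 reads, so whole reads were recovered. Reads per library, taken from the ppm that 1 read is worth, were lowest in SOB3-D (7637822 to 8877404) and highest in Col-0 (14488308 to 16075498). A level of 1 ppm stood for 7.64 to 16.1 reads, and a value of 0 allows up to 3 reads, or 0.187 to 0.393 ppm. Such floors cover counting error only.

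Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Transcripts with at least 1 ppm in at least 3 of the 12 libraries were kept, which left 25710 transcripts of 18502 genes. Values were tested as log2(ppm + 1) with limma 3.58.1 in R 4.3.3 (linear model with a mean-variance trend and robust empirical Bayes), 1 coefficient per genotype over all 12 libraries, with 8 residual degrees of freedom and a median of 21.3 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all kept transcripts, separately in each comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene is from this limma fit unless another tool is named. A gene was read through its representative transcript, the one with the highest mean ppm. All fold changes are on the log2(ppm + 1) scale, which understates the change of genes near or below 1 ppm. Where a genotype had 0 to a few reads of a gene, the change depends on the pseudocount. Levels are mean ± SD in ppm over n = 3 libraries. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

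The 4 comparisons were each altered genotype with Col-0 and sob3-6 with SOB3-D. The 25 gene lists, with 386 entries of which 385 loci were in the files, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. Each test was repeated with the correlation estimated from the data. Overlaps of called genes were set beside n1 × n2 / N and tested with Fisher's exact test. That test takes genes as independent units, which they are not. The comparisons also share the fitted spread of each gene, which can raise overlaps above n1 × n2 / N. Covariances of log2 changes were set beside 20 simulations of unchanged genotypes against shared Col-0 libraries. The simulations give overlaps of 0, which was not used, since unchanged genotypes are hardly ever called. The genes named are SOB3, ESC, PIF4, PIF5 and PIF7; the 6 with the largest positive and the 6 with the largest negative log2 change in each comparison among called genes whose 3 libraries did not overlap those of the other genotype; the 3 with the lowest p in each list with at least 2 called members; and the 6 of each overlap with the largest smaller change. Unless stated, all 3 libraries of one genotype lay beyond all 3 of the other for each gene said to have risen or fallen.

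Gene names and positions are from the TAIR10.1 annotation, which held 24747 of the loci. The deposited files hold no coordinates. Near-identical genes can share reads, so values of SAUR genes at the SAUR22 cluster, of RBCS, LHCB and AOC genes, of jacalin-like lectins, of AT5G26260 with AT5G26280 and of PCC1 with its neighbours AT3G22235 and AT3G22240 are uncertain as single-gene values.

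Alternatives tried were pseudocounts of 0.1 and 0.5, no filter, at least 5 ppm, quantile normalization, median-of-ratios scaling, a replicate block, a fit of only the 2 genotypes compared, empirical Bayes without robustness, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered whole reads, a 2-fold minimum, leaving out each library in turn and the estimated correlation. Thinning to the shallowest library, 1 transcript per gene and any transcript called were added after seeing the data. On simulated reads for sob3-6 and Col-0, over 25438 transcripts, the limma test recovered 72% of transcripts changed 1.5-fold, 94% at 2-fold, 92% at 4-fold and 100% at 8-fold, and 5 of its 184 calls were transcripts that had not been changed. In simulated lists over 18502 genes, camera called the raised list, and 6 of 200 random lists had an unadjusted p under 0.05. Genes were simulated independently of each other, so this does not test the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.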

Results

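The study asked which genes AHL and PIF transcription factors regulate in juvenile rosettes, and its title sets AHL factors against PIF4 in petiole growth. Transcript levels were measured by RNA-seq in the shoots of 14-day-old plants of the wild type Col-0, of the AHL lines SOB3-D and sob3-6 and of pif4 pif5 pif7, with 3 libraries per genotype. Depth was 14488308 to 16075498 reads in Col-0, 10179924 to 12567173 in sob3-6, 7637822 to 8877404 in SOB3-D and 13809707 to 14734732 in pif4 pif5 pif7. Replicates of a genotype correlated at r = 0.992 or above across transcripts, which are not independent of each other. They differed by more than sampling noise (chi-square per degree of freedom 1.88 to 3.62). The first principal component held 40.7% of the variance and placed SOB3-D at 31.3 to 32.3 and the other libraries at -18.6 to -4.53.

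The transcripts of the altered genes were examined in every genotype. SOB3 (AT1G76500, an AHL gene, chromosome 1, 28704963 to 28706691, TAIR10.1) was at 0.145 ± 0.16 ppm in Col-0 (SD, n = 3), with 7 reads in the 3 libraries together. It was at 0.19 ± 0.15 ppm in pif4 pif5 pif7. It rose to 196 ± 14 ppm in SOB3-D (log2 change 7.44, SE 0.10, limma adjusted p = 2.33e-30) and to 227 ± 8.4 ppm in sob3-6 (7.65, SE 0.10, adjusted p = 1.03e-30). Between these lines the difference was not called (0.21, SE 0.10, adjusted p = 0.106). SOB3 transcript was thus raised in both AHL lines, and protein function, on which the name dominant-negative rests, was not measured. ESC, a related AHL gene, was below the expression filter at 0.428 to 0.689 ppm. In pif4 pif5 pif7, PIF4 (AT2G43010, chromosome 2, 17886101 to 17889087) fell from 139 ± 6.1 to 77.4 ± 4.5 ppm (-0.84, SE 0.06, adjusted p = 5.6e-12). PIF5 (AT3G59060, chromosome 3, 21827905 to 21830837) fell from 193 ± 2.5 to 19.1 ± 2.3 ppm (-3.27, SE 0.06, adjusted p = 3.2e-24). PIF7 (AT5G61270, chromosome 5, 24638491 to 24640765) fell from 45.2 ± 1.4 to 6.48 ± 0.61 ppm (-2.63, SE 0.07, adjusted p = 7.1e-23). PIF4 rose in sob3-6 to 174 ± 9.8 ppm (0.32, SE 0.06, adjusted p = 0.00022) and was at 148 ± 11 ppm in SOB3-D (0.08, SE 0.06, adjusted p = 0.3). PIF7 rose in SOB3-D to 54 ± 2.6 ppm (0.25, SE 0.07, adjusted p = 0.0066), and was at 51.8 ± 1.9 ppm in sob3-6 (0.19, adjusted p = 0.058).

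**Figure D1:**
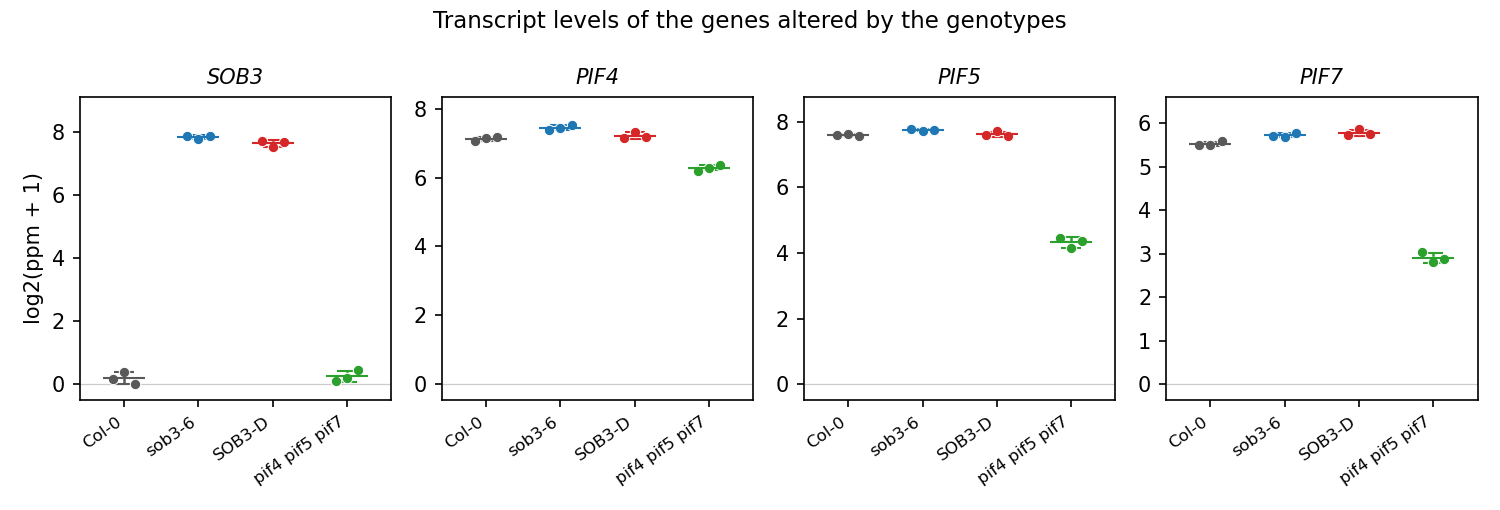
Level of SOB3, PIF4, PIF5 and PIF7 as log2(ppm + 1) in each genotype, where points are libraries, bars are means and error bars are SD (n = 3). SOB3 is near 0 in Col-0 and pif4 pif5 pif7 and above 7 in sob3-6 and SOB3-D, and PIF4, PIF5 and PIF7 are lowest in pif4 pif5 pif7.

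The dominant-negative mutant was compared with Col-0 to find AHL-regulated genes. In sob3-6, 10 of 16 glucosinolate and 4 of 11 salicylic acid defence genes rose, and 7 of 20 cell wall loosening genes fell. PCC1, a gene known for pathogen and circadian control, rose from 5.02 ± 3.3 to 84.1 ± 41 ppm (log2 change 3.81, SE 0.50, limma adjusted p = 0.0016). Its 3 sob3-6 libraries ranged from 38.1 to 116 ppm. Its neighbours AT3G22235 and AT3G22240 also rose. AT3G22235 went from 6.52 ± 3.3 to 90.3 ± 40 ppm (3.58, SE 0.42, adjusted p = 0.00097) and AT3G22240 from 3 ± 1.2 to 34 ± 16 ppm (3.04, SE 0.38, adjusted p = 0.001). The pseudogene AT4G08093 rose from 0.046 ± 0.08 to 7.08 ± 0.63 ppm (2.95, SE 0.17, adjusted p = 2.9e-13). LURP1, a gene induced by pathogens, rose from 0.343 to 5.85 ± 4.8 ppm (2.06, SE 0.46, adjusted p = 0.018). That call was lost when any single Col-0 library was left out (adjusted p = 0.0561 to 0.0591) and with only the 2 genotypes fitted (0.121). AT3G20370 fell from 21.7 ± 2 to 0.655 ± 0.16 ppm (-3.78, SE 0.16, adjusted p = 3.4e-10). QQS, an orphan gene linked to starch content, fell from 49.3 ± 5.6 to 3.07 ± 0.73 ppm (-3.64, SE 0.15, adjusted p = 9.7e-17). PYK10, the main beta-glucosidase of ER bodies, fell from 308 ± 39 to 62.3 ± 6.3 ppm (-2.29, SE 0.11, adjusted p = 8.2e-07). AT5G26280 (-2.48, adjusted p = 1.9e-07), AT1G52100 (-2.28, adjusted p = 4.2e-05) and AT1G14250 (-1.95, adjusted p = 1.6e-08) also fell.

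Among the gene lists in sob3-6, 10 of 16 glucosinolate genes rose and 0 fell (11 and 0 adjusted over the list alone). CYP79B3, which acts in indole glucosinolate synthesis, rose from 36 ± 3.5 to 52.4 ± 3 ppm (0.53, adjusted p = 1e-05). So did the activators of aliphatic glucosinolate genes MYB28 (0.29, adjusted p = 0.00013) and MYB29 (0.25, adjusted p = 0.0013). The glucosinolate list was called by camera (adjusted p = 4.7e-05), but not with an estimated correlation (adjusted p = 0.31). Of 20 cell wall loosening genes, 7 fell and 1 rose (9 and 3 adjusted over the list alone). The expansins EXPA11 (45.7 to 30.1 ppm, -0.58, adjusted p = 5.2e-07) and EXPA8 (220 to 168 ppm, -0.39, adjusted p = 4e-06) fell. So did XTH19, a xyloglucan endotransglucosylase gene (3.58 to 0.675 ppm, -1.45, adjusted p = 5.7e-07). That list was called with the preset correlation (adjusted p = 5.7e-06), with adjusted p = 0.056 when it was estimated. Of 11 salicylic acid defence genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone). The salicylic acid defence list had camera adjusted p = 0.0047, and adjusted p = 0.056 with an estimated correlation. Called members included NPR3, a salicylic acid receptor (14.3 to 21.7 ppm, 0.57, adjusted p = 0.00015), and WRKY54 (0.839 to 2.5 ppm, 0.91, adjusted p = 0.0018). Of 16 clock genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone). The clock list had camera adjusted p = 0.034, adjusted p = 0.13 with an estimated correlation and adjusted p = 0.11 after quantile normalization. With a replicate block that call was also lost. The 3 that fell were RVE1 (-0.51, adjusted p = 2.6e-06), GI (-0.55, adjusted p = 0.00012) and PRR9 (-0.44, adjusted p = 0.0011). Of 19 photosynthesis genes, 4 fell (6 adjusted over the list alone). The photosynthesis list had camera adjusted p = 0.034, and adjusted p = 0.40 with an estimated correlation, but under quantile normalization 3 rose and 1 fell and the list was not called. RCA, rubisco activase, fell from 12270 to 9852 ppm (-0.32, adjusted p = 1.8e-06), and was still called lower after quantile normalization.

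SAUR genes and PIF and shade targets were also counted in sob3-6, where 13.4% of all tested genes were called. None of 19 SAUR genes was called by limma (0 over all genes and 0 adjusted over the list alone), while the whole comparison had 4979 genes at an unadjusted p under 0.05. Of 19 PIF and shade targets, 2 fell and 1 rose (2 and 1 adjusted over the list alone). PAR2, a shade-induced inhibitor of elongation, fell (-0.79, adjusted p = 5.5e-05), and PRE1, a growth-promoting HLH gene, rose (0.44, adjusted p = 0.0059). The stomata list was called lower (adjusted p = 0.034, and 0.15 with an estimated correlation) with 0 of 8 members called alone. Of 10 brassinosteroid metabolism genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone). Of 14 light signalling genes, 2 rose and 1 fell (5 and 2 adjusted over the list alone). Of 18 cell cycle genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), including CYCD3;1, a G1 cyclin gene (0.30, adjusted p = 0.0009). None of these 3 lists was called by camera. Only 2 of 15 root markers passed the expression filter, and PYK10 fell while FRO2 was not called.

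In all, 1745 genes were higher and 730 lower in sob3-6 than in Col-0 of 18502 tested, and 33.2% of tested genes had libraries that did not overlap, against 10% by chance. The balance depended on scaling, since 70.5% of calls were higher with ppm as deposited, 39.2% after median-of-ratios scaling (809 higher, 1253 lower) and 46.5% after quantile normalization (896 and 1032). The count of higher genes fell to 1047 without Col-0 replicate 2, 1091 without Col-0 replicate 3, 1062 without sob3-6 replicate 2 and 976 without sob3-6 replicate 3.

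The AHL overexpressor was compared with Col-0 to find genes that change with AHL overexpression. In SOB3-D, 14 of 19 SAUR genes and 8 of 19 PIF and shade targets fell. The genes CYP79B2, CYP79B3, PYK10 and XTH31 rose. CYP79B2 and CYP79B3 code for enzymes that make indole acetaldoxime from tryptophan. CYP79B2 went from 28.6 ± 3.2 to 106 ± 8.3 ppm (1.86, SE 0.09, limma adjusted p = 6.6e-12). CYP79B3 went from 36 ± 3.5 to 96 ± 6.2 ppm (1.39, SE 0.07, adjusted p = 1.1e-13). PYK10 rose to 1327 ± 101 ppm (2.11, SE 0.11, adjusted p = 4.2e-07). The subtilase gene SBT4.12 rose from 0.0831 ± 0.095 to 18.7 ± 1.2 ppm (4.19, SE 0.16, adjusted p = 2.3e-18). AT2G32550 rose from 7.5 ± 0.73 to 87.4 ± 7.2 ppm (3.38, SE 0.11, adjusted p = 4.3e-20). PRR2 (AT4G13660), a pinoresinol reductase gene, rose from 0.44 to 11.3 ppm (3.12, SE 0.18, adjusted p = 4.8e-14). OMTF3 rose from 3.92 to 39 ± 4.3 ppm (3.02, SE 0.13, adjusted p = 3.9e-17). AT5G26260 also rose (3.04, adjusted p = 1.5e-06). QQS fell to 1.21 ± 0.28 ppm (-4.51, SE 0.15, adjusted p = 1.5e-19) and AT5G42530 from 98.2 ± 13 to 3.99 ± 0.53 ppm (-4.31, SE 0.31, adjusted p = 1.4e-05). The defence gene PBS3, which acts in salicylic acid synthesis (6.36 to 0.153 ppm, -2.68, adjusted p = 9.5e-13), fell. ACD6, which codes for an ankyrin protein that raises salicylic acid, fell from 10.6 ± 1.3 to 1.4 ± 0.32 ppm (-2.28, adjusted p = 2.6e-05). PCC1 was at 0.131, 0 and 0 ppm in the SOB3-D libraries (-2.40, adjusted p = 0.0073), and AT3G22235 fell likewise (-2.42, adjusted p = 0.003). Neither was called by edgeR on whole reads (adjusted p = 0.125 and 0.083). Of 11 salicylic acid defence genes on the list, 4 rose and 3 fell (4 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.75).

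In SOB3-D, 14 of 19 SAUR genes fell and 0 rose (16 and 0 adjusted over the list alone), with a median log2 change of -0.41. SAUR21 (-0.67, adjusted p = 6.8e-06), SAUR23 (-0.86, adjusted p = 8.1e-06) and SAUR22 (-0.94, adjusted p = 1.8e-05), small auxin-induced genes of cell expansion, were among them. The list was called by camera (adjusted p = 1.5e-05), though not with an estimated correlation (adjusted p = 0.22). Of 19 PIF and shade targets, 8 fell and 0 rose (11 and 0 adjusted over the list alone). The PIF and shade target list had camera adjusted p = 0.0027, and adjusted p = 0.20 with an estimated correlation. Called members included HAT1 (32.9 to 18.9 ppm, -0.77, adjusted p = 7.4e-10), IAA19 (7.21 to 3.04 ppm, -1.02, adjusted p = 1.3e-06) and LNG1, which promotes longitudinal cell growth (-0.33, adjusted p = 0.00033). Of 19 auxin response genes, 8 fell and 2 rose (8 and 2 adjusted over the list alone). The auxin response list had camera adjusted p = 0.026, and adjusted p = 0.25 with an estimated correlation. IAA2 fell (-0.58, adjusted p = 3.1e-06), and IAA17, an auxin response repressor, rose (40.4 to 71.3 ppm, 0.81, adjusted p = 1.1e-10). In contrast, 5 of 10 brassinosteroid metabolism genes rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.026, and 0.27 with an estimated correlation). The synthesis genes ROT3 (7.49 to 19.9 ppm, 1.3, adjusted p = 9.9e-11) and DWF4 (0.54, adjusted p = 4.9e-05) rose, and so did BAS1, which inactivates brassinosteroids (0.61, adjusted p = 0.00059).

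Of 20 cell wall loosening genes in SOB3-D, 9 fell and 2 rose (9 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.068). XTH31 rose from 84.8 ± 7.1 to 434 ± 16 ppm (2.34, SE 0.08, adjusted p = 6.7e-12), while XTH4 (-0.78, adjusted p = 2.5e-07) and XTH17 (-0.91, adjusted p = 8e-05) fell. GA3OX1, which makes bioactive gibberellin, rose from 5.42 to 15.2 ppm (1.34, adjusted p = 1.9e-09). Its gibberellin list, with 4 of 11 higher and 1 lower (4 and 1 adjusted over the list alone), was not called. Of 16 glucosinolate genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone). The glucosinolate list had camera adjusted p = 1.2e-05, and adjusted p = 0.27 with an estimated correlation. MYB34, an activator of indole glucosinolate genes, rose from 32.9 to 67.8 ppm (1.02, adjusted p = 4.7e-14). Of 12 flavonoid genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone). The flavonoid list had camera adjusted p = 0.0036, and adjusted p = 0.44 with an estimated correlation. Called members included PAP1, an anthocyanin regulator (0.78, adjusted p = 0.00034), and CHI (0.33, adjusted p = 0.0046; 0.0541 without Col-0 replicate 3). Of 15 jasmonate genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone). The jasmonate list had camera adjusted p = 0.026, and adjusted p = 0.38 with an estimated correlation. The jasmonate synthesis genes AOC1 (0.77, adjusted p = 2.7e-09) and OPR3 (0.46, adjusted p = 1.1e-05) rose and LOX3 (-0.63, adjusted p = 1.9e-05) fell. Of 19 photosynthesis genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). The photosynthesis list had camera adjusted p = 0.0067, and adjusted p = 0.33 with an estimated correlation, but 2 rose and 2 fell after quantile normalization. SOC1 fell from 57 ± 5.6 to 28.3 ± 2.1 ppm (-0.98, adjusted p = 7.1e-11) with AGL24 (-0.71, adjusted p = 1.7e-07) and FUL (-0.94, adjusted p = 0.00038). Of 10 floral genes in all, 3 fell and 2 rose (3 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.23). COR15A, a cold-induced chloroplast protein gene, fell from 44 ± 3.2 to 10.8 ± 3.3 ppm (-1.96, adjusted p = 0.0003) and COR413PM1 rose (0.73, adjusted p = 5.8e-06). AUR2, an Aurora kinase gene, rose (9.2 to 21.4 ppm, 1.13, adjusted p = 7.6e-10). In SOB3-D, 3 of 9 cold response genes rose and 2 fell, 1 of 18 cell cycle genes rose and 2 fell, and neither list was called (the same counts adjusted over the list alone).

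In all, 2139 genes were higher and 2748 lower in SOB3-D than in Col-0, and 37.9% of tested genes had libraries that did not overlap, against 10% by chance. No scaling moved the share of higher calls by over 10 percentage points, and no left-out library moved either count by over 1.5 times.

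**Figure D2:**
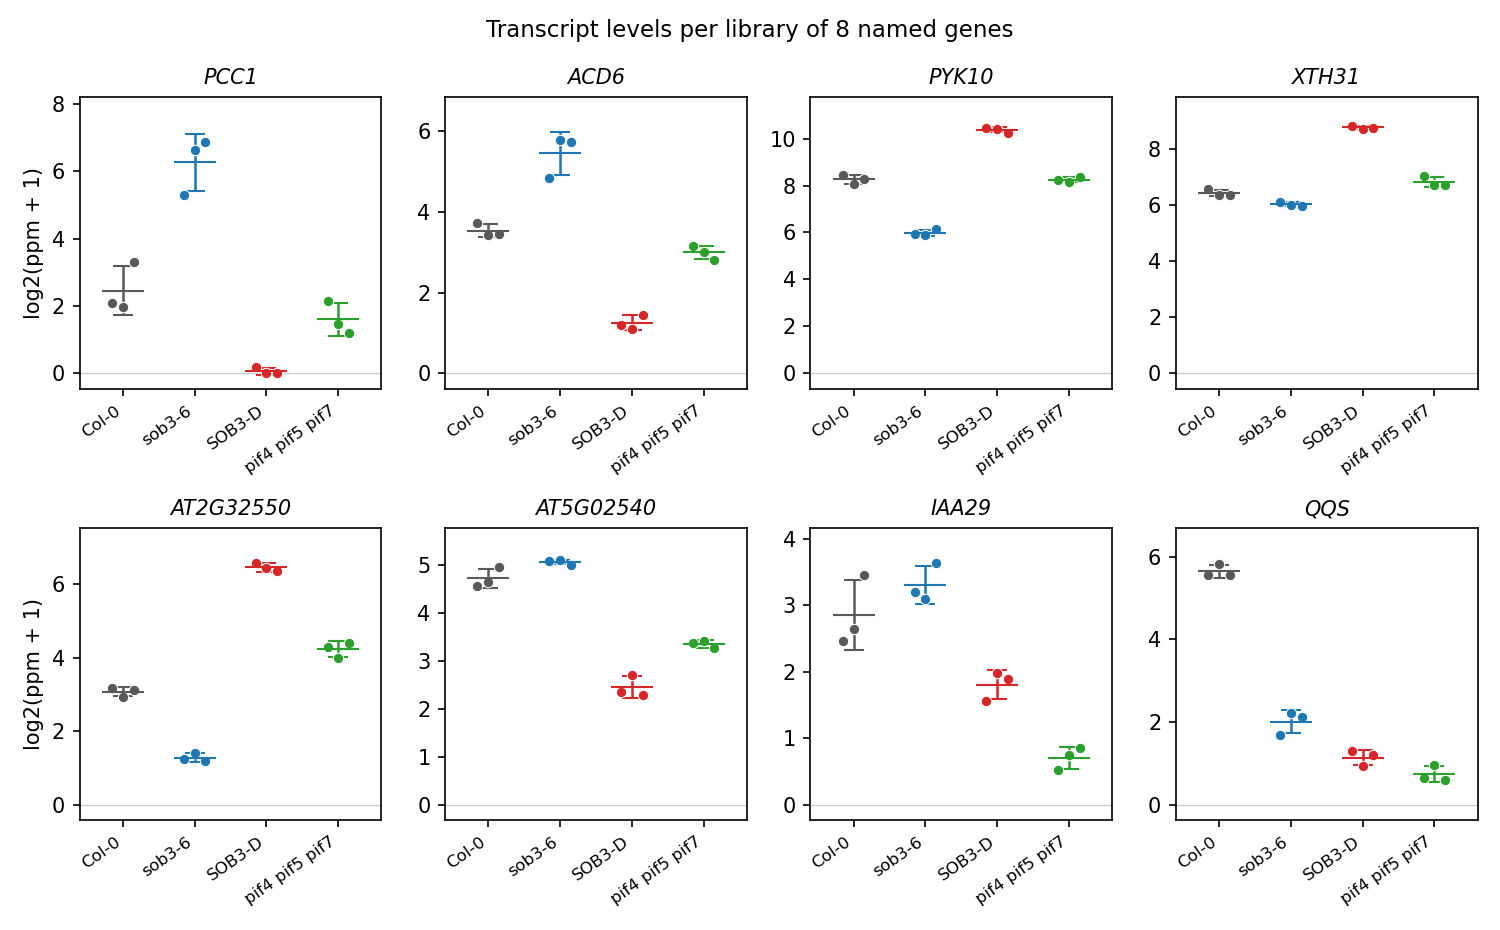
Level of PCC1, ACD6, PYK10, XTH31, AT2G32550, AT5G02540, IAA29 and QQS as log2(ppm + 1) in each genotype, where points are libraries, bars are means and error bars are SD (n = 3). PYK10 was at 62.3 ppm in sob3-6, 308 ppm in Col-0 and 1327 ppm in SOB3-D, and QQS was lower than in Col-0 in all 3 altered genotypes.

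The triple mutant was compared with Col-0 to find PIF-regulated genes. In pif4 pif5 pif7, 9 of 19 PIF and shade targets, 7 of 19 auxin response genes and 8 of 19 SAUR genes fell. Of the 277 genes that rose, 4 rose at least 2-fold. IAA29, an auxin response gene induced by shade, fell from 6.57 ± 2.9 to 0.635 ± 0.19 ppm (-2.15, SE 0.21, limma adjusted p = 3.1e-06). HFR1, a bHLH inhibitor of PIFs that shade induces, fell from 10.2 ± 1.3 to 1.68 ± 0.38 ppm (-2.07, SE 0.15, adjusted p = 5.9e-10). QQS fell to 0.676 ± 0.24 ppm (-4.91, SE 0.15, adjusted p = 5.7e-21) and AT5G24240 from 3.86 ± 0.57 to 0.141 ± 0.073 ppm (-2.08, SE 0.19, adjusted p = 6.4e-09). AT2G41640 rose from 7.55 ± 1.4 to 37.3 ± 0.52 ppm (2.18, SE 0.11, adjusted p = 3.4e-14). It lies at 17360374 to 17363788 on chromosome 2, within 1 Mb of PIF4. ARP9, an actin-related protein gene, rose from 16.6 ± 1.9 to 36.8 ± 2.4 ppm (1.11, SE 0.08, adjusted p = 4e-11) and AT2G32550 rose to 18 ± 2.8 ppm (1.15, SE 0.11, adjusted p = 8.9e-09). AT4G34550 rose (0.80, adjusted p = 0.0029), and so did AT3G20370 (0.76, adjusted p = 0.0083; 0.162 with only the 2 genotypes fitted).

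Of 19 PIF and shade targets in pif4 pif5 pif7, 9 fell and 0 rose (13 and 0 adjusted over the list alone). LNG1 fell (-0.54, adjusted p = 1.9e-06), as did IAA29 and HFR1. The list was called with the preset correlation (adjusted p = 3.1e-11) and with the estimated correlation (adjusted p = 0.0041). Of 19 auxin response genes, 7 fell and 0 rose (9 and 1 adjusted over the list alone). The auxin response list had camera adjusted p = 1.3e-05, and adjusted p = 0.020 with an estimated correlation. Called members included IAA19 (7.21 to 3.46 ppm, -0.88, adjusted p = 9.6e-05) and GH3.6, which conjugates auxin (-0.54, adjusted p = 0.0002). Of 19 SAUR genes, 8 fell and 0 rose (12 and 1 adjusted over the list alone). The SAUR list had camera adjusted p = 5.7e-06, and adjusted p = 0.13 with an estimated correlation. Examples were SAUR22 (-1.01, adjusted p = 5.2e-05), SAUR19 (-0.71, adjusted p = 0.00025) and SAUR65 (-0.66, adjusted p = 0.00038). Of 10 brassinosteroid metabolism genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone). The brassinosteroid metabolism list had camera adjusted p = 0.0068, and adjusted p = 0.14 with an estimated correlation. They were the synthesis genes CPD (179 to 130 ppm, -0.46, adjusted p = 6.4e-06) and BR6OX2 (-0.40, adjusted p = 0.00011). Of 20 cell wall loosening genes, 7 fell and 1 rose (8 and 3 adjusted over the list alone). The cell wall loosening list had camera adjusted p = 0.01, and adjusted p = 0.19 with an estimated correlation. Called members included EXPA11 (-0.56, adjusted p = 2.4e-06), XTH4 (177 to 111 ppm, -0.66, adjusted p = 1.5e-05) and XTH17 (-0.78, adjusted p = 0.003). Of 11 gibberellin genes, 1 fell (2 adjusted over the list alone). The gibberellin list had camera adjusted p = 0.042, and adjusted p = 0.14 with an estimated correlation.

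Of 16 glucosinolate genes in pif4 pif5 pif7, 8 fell and 0 rose (10 and 2 adjusted over the list alone). The glucosinolate list had camera adjusted p = 0.00046, and adjusted p = 0.26 with an estimated correlation. Called members included MYB29 (-0.28, adjusted p = 0.001) and CYP79F1, of aliphatic glucosinolate synthesis (411 to 337 ppm, -0.29, adjusted p = 0.0026). After quantile normalization 5 fell and 2 rose, and after median-of-ratios scaling 4 fell and 1 rose. Of 7 ethylene genes, 3 fell and 0 rose (6 and 0 adjusted over the list alone), including EBF2 (-0.28, adjusted p = 0.0026), but 1 fell after either scaling. The ethylene list had camera adjusted p = 0.0024, and adjusted p = 0.076 with an estimated correlation. Of 10 floral genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone), including SPL3 (-0.60, adjusted p = 0.0035), but 1 fell after quantile normalization and 2 after median-of-ratios scaling. The floral list had camera adjusted p = 0.03, and adjusted p = 0.14 with an estimated correlation. Of 9 cold response genes 3 fell (5 adjusted over the list alone), but 0 fell after quantile normalization or median-of-ratios scaling. The cold list had camera adjusted p = 0.00028, and adjusted p = 0.14 with an estimated correlation. Of 13 xylem genes 3 fell (7 adjusted over the list alone), but 1 fell after either scaling. The xylem list had camera adjusted p = 0.0022, and adjusted p = 0.17 with an estimated correlation. Of 12 flavonoid genes 1 rose (2 adjusted over the list alone). The flavonoid list was called higher by camera (adjusted p = 9.3e-09), but not with an estimated correlation (adjusted p = 0.14). The touch list was called higher with 0 of 12 members called (0 adjusted over the list alone; adjusted p = 0.0065, and adjusted p = 0.34 with an estimated correlation). Of 18 cell cycle genes 2 rose (2 adjusted over the list alone). The cell cycle list had camera adjusted p = 9.9e-07, and adjusted p = 0.14 with an estimated correlation. The cell cycle genes were AUR2 (0.44, adjusted p = 0.0077; 0.06 without Col-0 replicate 3) and KNOLLE (0.31, adjusted p = 0.0081; 0.0899 without pif4 pif5 pif7 replicate 3). Of 19 photosynthesis genes, 4 rose (4 adjusted over the list alone). The photosynthesis list had camera adjusted p = 6e-05, and adjusted p = 0.14 with an estimated correlation, but the list turned lower and was not called after quantile normalization. The photoreceptor gene PHYA fell (-0.35, adjusted p = 0.00039) and HYH rose (0.40, adjusted p = 0.0048), in a light signalling list with 1 of 14 higher and 2 lower (1 and 2 adjusted over the list alone) that was not called.

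In all, 277 genes were higher and 894 lower in pif4 pif5 pif7 than in Col-0, and 27.1% of tested genes had libraries that did not overlap, against 10% by chance. The excess of lower genes depended on scaling, with 23.7% of calls higher as deposited, 48.3% after median-of-ratios scaling (532 higher, 569 lower) and 42.7% after quantile normalization (411 and 551). Counts of higher genes fell to 174 without Col-0 replicate 2, 131 without Col-0 replicate 3, 131 without pif4 pif5 pif7 replicate 1 and 181 without pif4 pif5 pif7 replicate 3. Counts of lower genes fell to 509 without Col-0 replicate 3 and 521 without pif4 pif5 pif7 replicate 1.

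The mutant and the overexpressor were also compared with each other, without Col-0. Of 19 SAUR genes, 14 were higher in sob3-6, and 8 of 12 flavonoid and 4 of 8 stomata genes were lower. PCC1 (6.2, SE 0.50, limma adjusted p = 1.9e-05), AT3G22235 (6.00, SE 0.42, adjusted p = 8.1e-06) and AT3G22240 (4.32, SE 0.38, adjusted p = 2.5e-05) were higher in sob3-6. ACD6 was at 44.9 ± 15 ppm in sob3-6 and 1.4 ± 0.32 ppm in SOB3-D (4.21, SE 0.23, adjusted p = 1.2e-07). AT5G42530 was at 160 ± 62 and 3.99 ± 0.53 ppm (4.93, SE 0.31, adjusted p = 4.2e-06). PBS3 was at 8.85 and 0.153 ppm (3.1, SE 0.17, adjusted p = 1.8e-14). AT2G32550 was at 1.43 ± 0.21 ppm in sob3-6 and 87.4 ± 7.2 ppm in SOB3-D (-5.18, SE 0.11, adjusted p = 3.9e-25). PYK10 (-4.39, SE 0.11, adjusted p = 1e-09) and the lectin gene JAL33, at 3.98 and 98.4 ppm (-4.32, SE 0.12, adjusted p = 2.6e-14), were lower in sob3-6. So were AT5G26280 (-4.53, adjusted p = 3.9e-11), SBT4.12 (-4.18, adjusted p = 1.1e-18) and AT3G44970, at 3.87 and 84.1 ppm (-4.12, adjusted p = 2e-15).

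Of 19 SAUR genes, 14 were higher and 0 lower in sob3-6 than in SOB3-D (15 and 0 adjusted over the list alone). The SAUR list had camera adjusted p = 4e-04, and adjusted p = 0.25 with an estimated correlation. Called members included SAUR22 (1.31, adjusted p = 5.7e-08) and SAUR65 (0.83, adjusted p = 1.5e-06). Of 19 PIF and shade targets, 10 were higher and 2 lower (10 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.093). HAT1 (0.59, adjusted p = 7.9e-08) and IAA29 (9.04 against 2.53 ppm, 1.5, adjusted p = 2.3e-05) were higher. Of 12 flavonoid genes, 8 were lower and 0 higher (8 and 0 adjusted over the list alone). The flavonoid list had camera adjusted p = 6e-05, and adjusted p = 0.40 with an estimated correlation. PAP1 (-0.90, adjusted p = 4.2e-05) and CHI (-0.43, adjusted p = 0.00022) were examples. Of 10 brassinosteroid genes, 5 were lower and 1 higher (5 and 1 adjusted over the list alone). The brassinosteroid list had camera adjusted p = 0.02, and adjusted p = 0.25 with an estimated correlation. Called members included ROT3 (-1.16, adjusted p = 7.8e-10) and BAS1 (-0.91, adjusted p = 1.9e-06). Of 16 glucosinolate genes, 7 were lower and 4 higher (8 and 5 adjusted over the list alone), and CYP79B2 was lower (-1.45, adjusted p = 1.7e-10). The glucosinolate list had camera adjusted p = 0.02, adjusted p = 0.52 with an estimated correlation and adjusted p = 0.055 after quantile normalization. Of 8 stomata genes, 4 were lower and 1 higher (4 and 1 adjusted over the list alone). The stomata list had camera adjusted p = 0.024, and adjusted p = 0.25 with an estimated correlation. Lower genes included SLAC1, a guard cell anion channel gene (-0.80, adjusted p = 5e-06), and SPCH, which starts the stomatal lineage (-0.49, adjusted p = 0.0025). Of 19 photosynthesis genes, 14 were lower and 0 higher (15 and 0 adjusted over the list alone). The photosynthesis list had camera adjusted p = 3e-05, and adjusted p = 0.25 with an estimated correlation, but 0 were called either way after quantile normalization.

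GA3OX1 (-1.73, limma adjusted p = 6.1e-12) and XTH31 (-2.73, adjusted p = 5.4e-13) were lower in sob3-6 than in SOB3-D. NPR3 (1.16, adjusted p = 1.1e-10), WRKY70 (9.32 against 1.97 ppm, 1.78, adjusted p = 0.00046), SOC1 (0.86, adjusted p = 6.8e-10) and COR15A (1.95, adjusted p = 0.00024) were higher. None of the gibberellin (2 higher and 4 lower of 11), salicylic acid (5 and 1 of 11), floral (4 and 1 of 10) and cold lists (2 and 4 of 9) was called in that comparison. Of the 2 root markers tested, PYK10 was lower and FRO2 higher (adjusted p = 0.041 for the list, 0.25 with an estimated correlation and 0.071 after quantile normalization). The FRO2 call was lost without sob3-6 replicate 1 (adjusted p = 0.0806), without SOB3-D replicate 1 (0.122), after thinning (0.14) and with edgeR (0.084) or DESeq2 (0.171). In all, 4591 genes were higher and 2016 lower in sob3-6 than in SOB3-D, and 44.1% of tested genes had libraries that did not overlap, against 10% by chance. The excess of higher genes turned with scaling, from 69.5% as deposited to 47.5% after median-of-ratios scaling (2639 higher, 2914 lower) and 53.3% after quantile normalization (2968 and 2596).

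**Figure D3:**
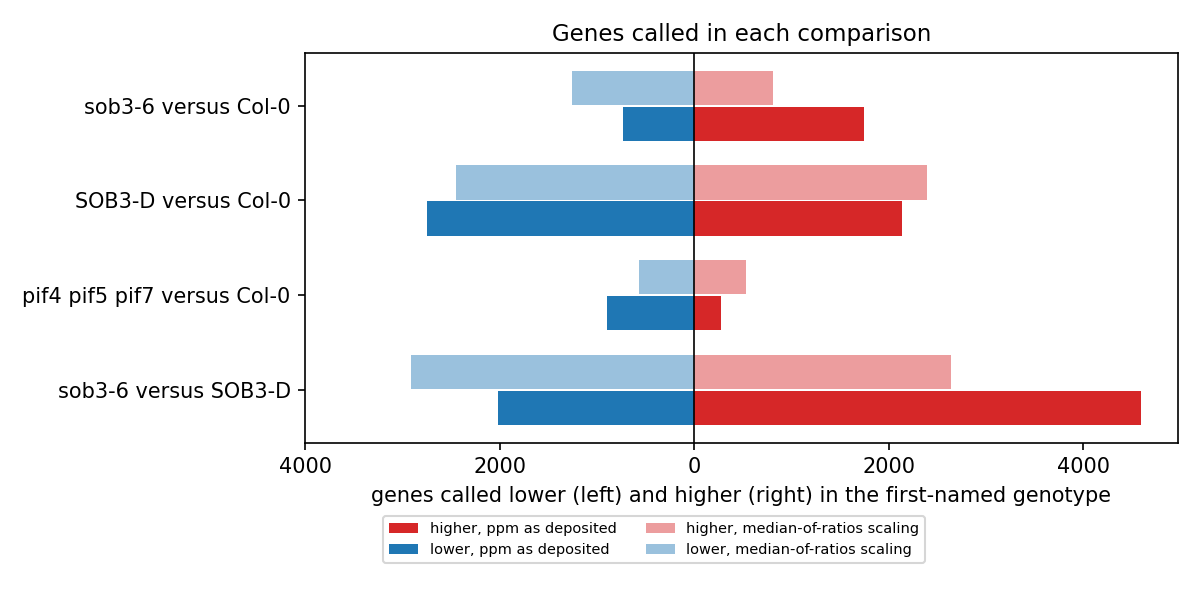
Number of genes called higher or lower in each of the 4 comparisons (limma, adjusted p under 0.05, of 18502 genes), with ppm as deposited in solid bars and after median-of-ratios scaling in pale bars. In sob3-6 against Col-0 the counts go from 1745 higher and 730 lower to 809 and 1253.

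**Figure D4:**
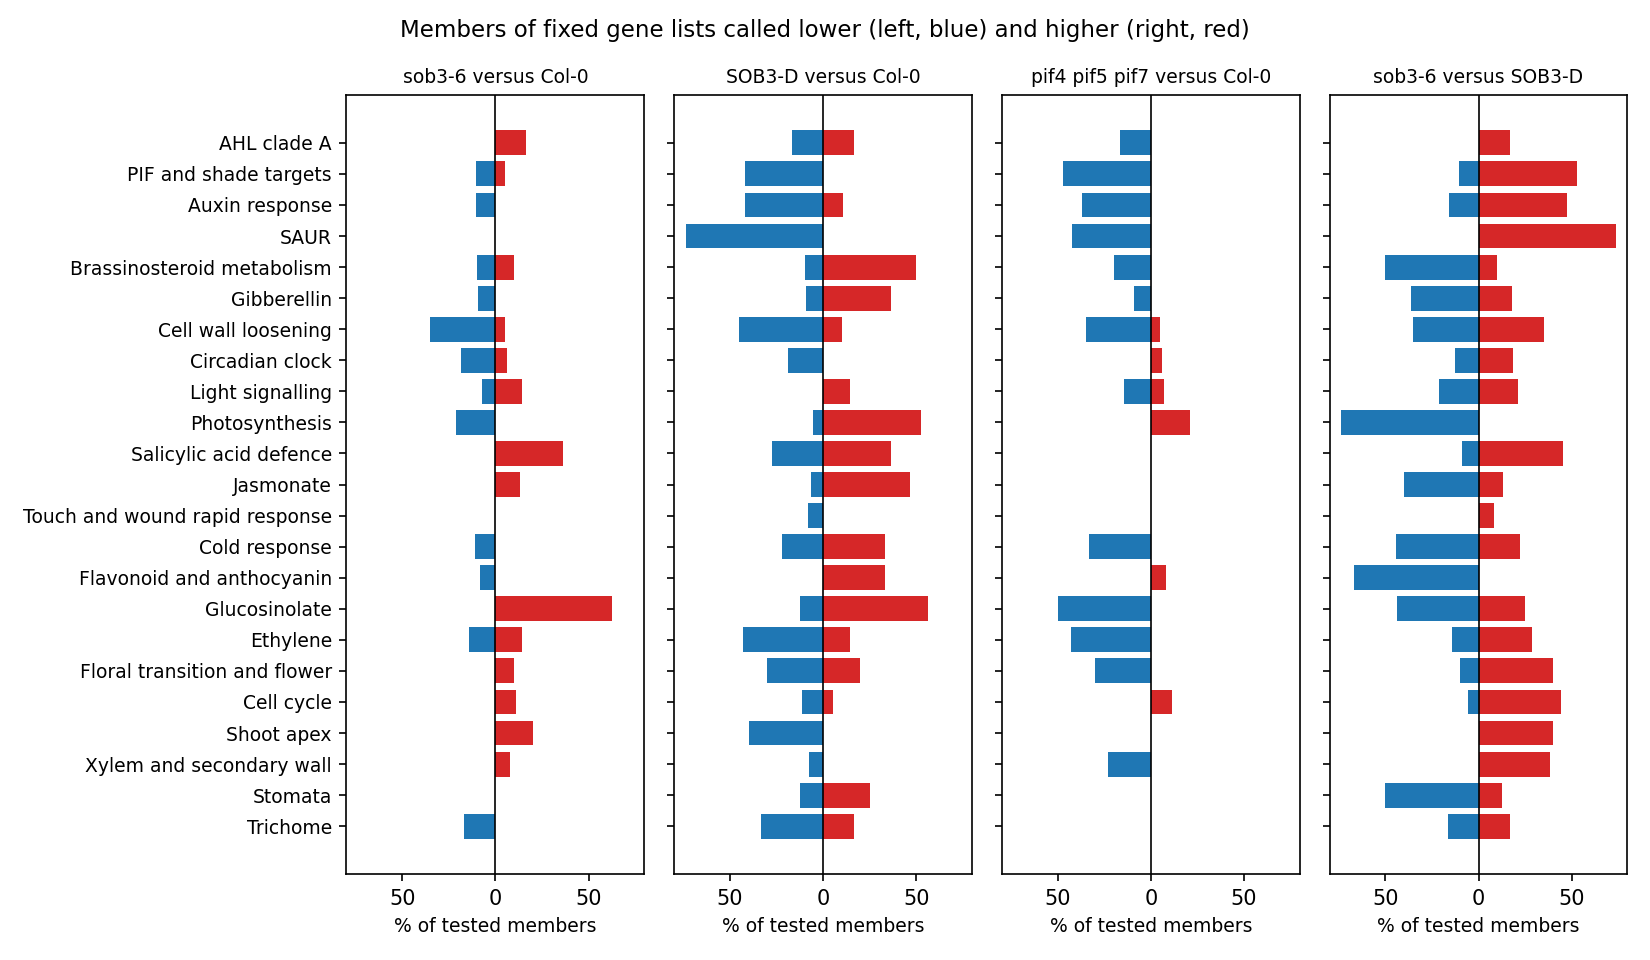
Percent of the tested members of each gene list that were called lower (left, blue) or higher (right, red) in each of the 4 comparisons with ppm as deposited. The lists of altered genes and of root markers are not drawn. SAUR genes were lower in SOB3-D (14 of 19) and pif4 pif5 pif7 (8 of 19), and photosynthesis genes went after quantile normalization from 4 lower to 3 higher and 1 lower in sob3-6, from 10 higher and 1 lower to 2 and 2 in SOB3-D, from 4 to 1 higher in pif4 pif5 pif7 and from 14 to 0 lower in sob3-6 against SOB3-D.

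At the preset correlation, 40 of 100 list tests were called, and 3 were called with an estimated correlation. All 3 were in pif4 pif5 pif7: PIF and shade targets, auxin response and the altered genes themselves, which are not independent evidence. The PIF and auxin lists both hold IAA19 and IAA29, each called lower there, so these list calls are not independent of each other. That list of altered genes was also called higher in sob3-6 (adjusted p = 6.6e-06, and 0.053 with an estimated correlation) and in SOB3-D (0.0027 and 0.20). The root marker list was called lower in sob3-6 (adjusted p = 0.00081, and 0.056 with an estimated correlation). Median, mean and test differed in sign for auxin response, brassinosteroid metabolism, light signalling, touch, floral and trichome genes in sob3-6. They also differed for AHL, salicylic acid, cold, ethylene and trichome genes in SOB3-D, for AHL, clock, light signalling, root and shoot apex genes in pif4 pif5 pif7 and for jasmonate, cold and ethylene genes between the AHL lines. None of those lists was called by camera in the comparison named.

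The title's opposition of AHL factors and PIF4 was examined as the genes changed in both kinds of genotype. Of the genes lower in pif4 pif5 pif7 than in Col-0, 395 were also higher in sob3-6 than in SOB3-D. These comparisons share no library, and independent lists would share 222 genes (1.78 times, Fisher's exact test, two-sided, p = 2.5e-38). Genes are not independent units, so the p-values of such overlaps do not measure the spread between libraries. Both comparisons came from the same fit with a shared spread per gene, so a gene of small spread is more easily called in both. The number for independent lists can therefore be too low a reference, here and in the overlaps below. The 395 genes included IAA29 (1.5 between the AHL lines, -2.15 in pif4 pif5 pif7), AT5G02540 (2.61 and -1.37) and FLS2, the flagellin receptor gene (1.77 and -1.17). AT5G22580 (1.6 and -1.25) and AT1G52190 (1.24 and -1.26) were also among them. In the other direction, 105 genes were lower in sob3-6 than in SOB3-D and higher in pif4 pif5 pif7, against 30.2 for independent lists (3.48 times, Fisher's exact test, p = 1.7e-32). Among them were AT2G32550, AT2G41640 (-1.13 and 2.18), ARP9 (-1.17 and 1.11) and AT3G44970. Across genes, the log2 changes of the pair of comparisons correlated at r = -0.18 (Spearman -0.13; covariance -0.0121, simulated 1.8e-05). After median-of-ratios scaling the overlaps were 213 against 81.2 and 218 against 83.8. The 395 fell to 251 without Col-0 replicate 3 and 240 without pif4 pif5 pif7 replicate 1, and the 105 to 50 and 59. Counted after these results were seen, 116 genes were lower in both comparisons (97.4 for independent lists; 64 and 74 without the same libraries) and 54 higher in both (68.7). The 54 became 25 and 26 without Col-0 replicates 2 and 3, 35 without sob3-6 replicate 1, and 19 and 24 without pif4 pif5 pif7 replicates 1 and 3.

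Against the shared Col-0 libraries, 275 genes were lower in both SOB3-D and pif4 pif5 pif7 (133 for independent lists) and 58 higher in both (32). Genes changed in opposite directions, counted after these results were seen, were also in excess, with 71 lower in SOB3-D and higher in pif4 pif5 pif7 (41.1) and 146 the other way (103). AT5G02540 fell from 25.4 ppm to 4.48 ppm in SOB3-D (-2.27, limma adjusted p = 9.5e-16) and 9.16 ppm in pif4 pif5 pif7 (-1.37, adjusted p = 2.8e-10). FLS2 fell from 25.5 to 7.5 ppm (-1.63, adjusted p = 1e-10) and 10.8 ppm (-1.17, adjusted p = 2e-07). ARP9 rose in both (1.18 and 1.11). Genes higher in sob3-6 and lower in pif4 pif5 pif7 numbered 207 (84.3 for independent lists). They included the wall-associated kinase gene WAK2 (0.69, adjusted p = 3.4e-07, and -0.73, adjusted p = 2e-07) and the linker histone gene HIS1-3 (1.12, adjusted p = 2.7e-07, and -0.74, adjusted p = 0.00036). Genes lower in sob3-6 and higher in pif4 pif5 pif7 numbered 87 (10.9 for independent lists), including AT2G32550 and AT4G34550 (-1.18 and 0.80). In the same direction, 61 genes were lower in both sob3-6 and pif4 pif5 pif7 (35.3) and 17 higher in both (26.1). In the AHL lines, 218 genes were higher in sob3-6 and lower in SOB3-D (259 for independent lists), among them ACD6 (1.93, adjusted p = 0.00033, in sob3-6). The reverse held for 137 genes (84.4 for independent lists), among them PYK10, JAL33 (-1.91 and 2.41), JAL22 (-1.84 and 1.93) and AT1G14250 (-1.95 and 2.02). In contrast, 338 genes were higher in both AHL lines (202 for independent lists) and 256 lower in both (108).

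The 3 Col-0 libraries cannot be split, and shared controls move both comparisons the same way, so part of an excess in the same direction can come from them. The covariance of log2 changes across genes was 0.00696 for sob3-6 with SOB3-D, -0.000355 for sob3-6 with pif4 pif5 pif7 and 0.0118 for SOB3-D with pif4 pif5 pif7, against 0.0055 simulated from shared controls alone. The value for sob3-6 with SOB3-D, like its correlation, includes SOB3, itself raised in both AHL lines, and was not computed without it. Its excess over 0.0055 can therefore not be read as a shared response. The correlations were 0.10, -0.01 and 0.20 (Spearman 0.20, -0.04 and 0.11). Simulated correlations were 0.41, 0.46 and 0.43, but unchanged genotypes lack the variance of real changes. Those correlations are therefore no reference for the observed ones, and only the covariances can be compared. After median-of-ratios scaling, 112 genes were higher in sob3-6 and lower in SOB3-D (107 for independent lists), so the shortfall of 218 against 259 was not seen, and 225 were the reverse (162). In sob3-6 and pif4 pif5 pif7, 82 and 169 were then opposite (24.9 and 36). In SOB3-D and pif4 pif5 pif7, 186 were lower in both (75.3), 110 higher in both (68.6), 143 lower in SOB3-D and higher in pif4 pif5 pif7 (70.4) and 93 the other way (73.4). Without Col-0 replicate 3, the 275 and 58 genes of SOB3-D with pif4 pif5 pif7 became 167 and 28, and without pif4 pif5 pif7 replicate 1 they became 178 and 32. The 207 genes became 111, 107 and 98 without Col-0 replicates 1, 2 and 3, 135 and 122 without sob3-6 replicates 2 and 3, and 133 without pif4 pif5 pif7 replicate 1. The 87 became 47, 46 and 31 without Col-0 replicates 1, 2 and 3, and 45 and 49 without pif4 pif5 pif7 replicates 1 and 2. The 218 became 128, 120 and 131 without Col-0 replicates 1, 2 and 3, and 140 and 141 without sob3-6 replicates 2 and 3, and the 137 became 90 without Col-0 replicate 3. The 146 became 77, 86 and 67 without Col-0 replicates 1, 2 and 3 and 91 without pif4 pif5 pif7 replicate 1. The 71 became 39, 32 and 29 without Col-0 replicates 1, 2 and 3, and 28, 44 and 44 without pif4 pif5 pif7 replicates 1, 2 and 3. The 338 became 209 and 191 without Col-0 replicates 2 and 3, and 222 and 208 without sob3-6 replicates 2 and 3. The 61 became 40 and 29 without Col-0 replicates 2 and 3. The 17 became 10 without Col-0 replicate 3, 11 without sob3-6 replicate 2, 32 without SOB3-D replicate 2, and 8 and 7 without pif4 pif5 pif7 replicates 1 and 3.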

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

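Thinning to the shallowest library, 1 transcript per gene and any transcript called were chosen after the data were seen. Over 304 named gene effects, of which 295 were called, 5333 values under the alternatives kept their direction and their side of the threshold, 370 fell short of it, 6 newly passed and 3 turned sign. The 3 that turned did so under quantile normalization, and none of them was called there: RBCS3B in sob3-6 (0.0614, adjusted p = 0.36), RBCS1A in pif4 pif5 pif7 (-0.0535, adjusted p = 0.46) and LHCA1 in sob3-6 against SOB3-D (0.0171, adjusted p = 0.745). Every call of the report that edgeR also made had the same direction there. Of the calls reported, edgeR on whole reads made 1018 of 1745 higher and 730 of 730 lower in sob3-6. It made 2121 of 2139 and 2282 of 2748 in SOB3-D, and 277 of 277 and 715 of 894 in pif4 pif5 pif7. For sob3-6 against SOB3-D it made 2362 of 4591 higher and 2002 of 2016 lower. DESeq2 made 494 of 1745 and 691 of 730 in sob3-6, and 1713 of 2139 and 1669 of 2748 in SOB3-D. It made 266 of 277 and 437 of 894 in pif4 pif5 pif7, and 1646 of 4591 and 1891 of 2016 for sob3-6 against SOB3-D. Scaling sets the balance of higher and lower genes, since the median-of-ratios factors of sob3-6 and of pif4 pif5 pif7 lie on opposite sides of those of Col-0. Depth limits low genes most, as 1 ppm stands for 7.64 reads in the shallowest library and 16.1 in the deepest. For the counts that moved by over 1.5 times, the cause was not tested beyond this.

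With a 2-fold minimum, which only removes genes, the counts higher and lower were 24 and 48 in sob3-6, 184 and 86 in SOB3-D, 4 and 27 in pif4 pif5 pif7 and 147 and 245 in sob3-6 against SOB3-D. The overlaps were then 6 (sob3-6 higher, SOB3-D lower) and 16 (the reverse), 2 (sob3-6 higher, pif4 pif5 pif7 lower) and 1 (the reverse), 12 (lower in SOB3-D and pif4 pif5 pif7) and 2 (higher in both), and 11 and 3 between the AHL lines' contrast and pif4 pif5 pif7. Median-of-ratios scaling gave 809 higher and 1253 lower in sob3-6, 532 and 569 in pif4 pif5 pif7 and 2639 higher in sob3-6 than SOB3-D, with overlaps of 112, 225, 82, 169, 110 (higher in SOB3-D and pif4 pif5 pif7), 213 and 218 in the same order. Quantile normalization gave 896 higher in sob3-6, 551 lower in pif4 pif5 pif7 and 2968 higher in sob3-6 than SOB3-D, with overlaps of 131 (sob3-6 higher, SOB3-D lower), 101 (sob3-6 higher, pif4 pif5 pif7 lower), 95 (higher in SOB3-D and pif4 pif5 pif7), 233 and 162. edgeR gave 1019 higher and 1366 lower in sob3-6, 688 higher in pif4 pif5 pif7 and 2362 higher in sob3-6 than SOB3-D, with overlaps of 130, 233, 108, 213, 126 (higher in SOB3-D and pif4 pif5 pif7), 249 and 251. DESeq2 gave 499 higher in sob3-6, 1685 lower in SOB3-D, 480 higher and 466 lower in pif4 pif5 pif7 and 1649 higher in sob3-6 than SOB3-D, with overlaps of 75 (sob3-6 higher, SOB3-D lower), 58 and 154 (sob3-6 and pif4 pif5 pif7, opposite), 146 (lower in SOB3-D and pif4 pif5 pif7), 166 and 180. Thinning gave 132 genes higher in sob3-6 and lower in SOB3-D and 125 higher in sob3-6 and lower in pif4 pif5 pif7. Without a filter, 55 genes were lower in sob3-6 and higher in pif4 pif5 pif7, and with only the 2 genotypes fitted 480 were higher in pif4 pif5 pif7. Of 40 list calls, 3 were made with the estimated correlation and 33 were kept after quantile normalization.

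The replicate numbers are not known to pair the libraries. Deviations of same-numbered libraries correlated at -0.045 to 0.13, over 0.1 in 4 of 18 pairs, and 8 of 12 libraries were closest to their own number. That is more than randomly assigned numbers would give on average. All pairs of replicates 1 and all of replicates 3 were above 0, and those of replicates 2 ran from -0.045 to 0.078. A batch shared by number is therefore not excluded. With a replicate block, 504 genes were higher in pif4 pif5 pif7, and the overlaps were 311 (sob3-6 higher, pif4 pif5 pif7 lower), 139 (the reverse), 113 (higher in SOB3-D and pif4 pif5 pif7) and 181 (lower in sob3-6 than SOB3-D, higher in pif4 pif5 pif7). The block moved no other count by over 1.5 times, and of the list calls only that of the clock list in sob3-6 was lost (adjusted p = 0.061).

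Leaving out 1 library of the genotypes compared at a time, counts higher and lower ranged from 976 to 1335 and 507 to 607 in sob3-6, 1738 to 1939 and 2080 to 2542 in SOB3-D, 131 to 204 and 509 to 690 in pif4 pif5 pif7, and 3632 to 4214 and 1764 to 1868 in sob3-6 against SOB3-D. Of the reported calls, 613 of 1745 and 351 of 730 in sob3-6, 1270 of 2139 and 1616 of 2748 in SOB3-D, 77 of 277 and 339 of 894 in pif4 pif5 pif7, and 2703 of 4591 and 1352 of 2016 between the AHL lines were kept whichever of those libraries was left out. The overlaps then ranged from 120 to 226 (sob3-6 higher, SOB3-D lower) and 90 to 140 (the reverse; 144 at most with a library of pif4 pif5 pif7 left out), from 98 to 183 (sob3-6 higher, pif4 pif5 pif7 lower) and 31 to 83 (the reverse; 268 and 111 at most with a library of SOB3-D left out), from 167 to 312 (lower in SOB3-D and pif4 pif5 pif7) and 28 to 79 (higher in both), and from 240 to 463 and 50 to 132 between the contrast of the AHL lines and pif4 pif5 pif7. The libraries that moved a count by over 1.5 times are named in the comparisons.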

Other observations

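The ER-body gene list, the families grouped by gene symbol and the tests of the range of Col-0 libraries and of chance for QQS, AT5G24240 and AT4G10695 were chosen only after the results were seen. ER bodies are compartments that store beta-glucosidases. Of 13 of their genes tested, 8 fell in sob3-6, 12 rose in SOB3-D and 8 did both, while 2 were called in pif4 pif5 pif7. The list as a whole was not tested for enrichment. NAI2, an ER-body protein gene, fell from 83.9 ppm in Col-0 to 29.6 ppm in sob3-6 (-1.47, limma adjusted p = 3.3e-07) and rose to 174 ppm in SOB3-D (1.05, adjusted p = 2.6e-06). PBP1 (-1.68 and 1.15) and JAL31 (-1.51 and 1.85) did the same, while JAL23 rose in sob3-6 (1.15) and fell in pif4 pif5 pif7 (-1.12), calls that were lost without single libraries.

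Among families grouped by gene symbol, which can mix unrelated genes, 10 of 18 GRF genes rose in sob3-6 (camera adjusted p = 4.5e-05, and 0.84 with an estimated correlation). In SOB3-D, 50 of 110 EMB genes, named for embryo-lethal mutants, fell and 1 rose (adjusted p = 2.1e-07, and 0.13 with an estimated correlation), with 14 of 21 RPL (5.6e-06 and 0.41), 11 of 22 RPS (7.3e-05 and 0.39) and 11 of 14 PTAC genes (5.2e-04 and 0.31) lower. In sob3-6 against SOB3-D, 16 of 23 CRK receptor kinase genes were higher and 3 lower (0.0054 and 0.44). In pif4 pif5 pif7, 5 of 10 HTA histone genes rose (2.1e-06 and 0.58). These families were not examined under other scalings.

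QQS, AT5G24240 and AT4G10695 were lower than in Col-0 in all 3 altered genotypes, with AT4G10695 at 1.78 ppm in Col-0, 0.166 ppm in sob3-6, 0.242 ppm in SOB3-D and 0.0465 ppm in pif4 pif5 pif7. They are the 3 called in every altered genotype among 11 genes at least 2-fold apart from Col-0 in the same direction in each. In 20 simulations of unchanged genotypes sharing the Col-0 libraries, at most 1 gene was that far apart in all 3. This argues against chance values of the shared controls for the 3 called genes, and QQS was at 46 to 55.8 ppm in the Col-0 libraries and at most 3.63 ppm in every other. For the 11 as a whole chance cannot be told apart, because the other 8 were not called in all 3 and vary within genotypes (AT2G07688 from 9.56 to 60.3 ppm in SOB3-D). A single aberrant Col-0 library is argued against for these 3 genes, since the range of their Col-0 libraries was at most 0.33 of the smallest change. For the 11 genes the median ratio was 0.62 and an aberrant library cannot be told apart. Of them, 5 are organelle-encoded and vary within every genotype (ATCG00020 from 57.5 to 358 ppm in SOB3-D). AT2G07688 varied together with ATCG00020 over the libraries (60.3 and 358 ppm in SOB3-D replicate 2), so they may share reads. AT2G07706 and AT2G07732 were also highest within SOB3-D in replicate 2 (33.6 and 64 ppm). All 8 uncalled genes peaked there within SOB3-D and fell from replicate 1 to 3 in sob3-6 and pif4 pif5 pif7. They may therefore be 1 signal rather than 8. A difference in the Col-0 seed stock, a heritable epigenetic state of QQS and an effect common to the genotypes may each account for the 3 genes, and all stay open and untested.

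PYK10 and 7 other ER-body genes of the 13 tested were lower in sob3-6 and higher in SOB3-D. PYK10 is abundant in roots, while the harvest, per the labels, was the shoot above a cut through the hypocotyl. That cut leaves out roots, but root tissue remaining in the SOB3-D harvest was not measured well enough to exclude it. The 14 root markers other than PYK10 summed to 1.7 to 3.51 ppm in the SOB3-D libraries and 3.54 to 4.33 ppm in the sob3-6 libraries (0.727 times as much), while PYK10 was 21 times as high in SOB3-D. The 1 other root marker kept, FRO2, was higher in sob3-6 by 0.55, a call lost without sob3-6 replicate 1 (limma adjusted p = 0.0806) or SOB3-D replicate 1 (0.122). FRO2 makes up most of the difference in the sums, and the other 13 were below the expression filter. The summed markers thus did not rise with PYK10, but values this low cannot exclude root tissue. NAI1, the transcription factor that PYK10 needs, was lower in sob3-6 than in SOB3-D (-0.77, limma adjusted p = 6.6e-05), which is consistent with its level being part of the change. NAI1 was not called lower in sob3-6 than in Col-0 (-0.19, adjusted p = 0.4), so the hypothesis has no measured step for that side.

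Within 100 kb of SOB3, 5 of 42 tested genes were called in the same direction in sob3-6 and SOB3-D, against 588 of 18456 elsewhere (odds ratio 4.11, 95% interval 1.26 to 10.5, Fisher's exact test, two-sided, p = 0.011). They are OPR1 (0.45 in sob3-6 and 0.46 in SOB3-D), OPR2 (0.48 and 0.82), HMG1 (0.25 and 0.46), AT1G76530 (-0.61 and -0.55) and AT1G76280 (-0.25 and -0.26). Activation sequence inserted near SOB3 in both lines could raise the first 3, but 2 of the 5 fell, which it would not explain, and OPR1 and OPR2 can share reads. AT1G76510 and AT1G76520 lie nearer to SOB3 than OPR1 and OPR2. They were called higher in sob3-6 (0.27 and 0.48) but not in SOB3-D (0.14, limma adjusted p = 0.29, and -0.06, adjusted p = 0.74). The explanation stays open. An effect of the SOB3 protein on its neighbours was not tested.

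Within 1 Mb of PIF4, PIF5 and PIF7, 72 of 1235 tested genes were called in pif4 pif5 pif7, against 1096 of 17263 elsewhere (odds ratio 0.913, 95% interval 0.704 to 1.17, Fisher's exact test, two-sided, p = 0.51). Among the 72 are AT2G41640 (2.18) and, near PIF7, AT5G61280 (chromosome 5, 24643556 to 24644990). AT5G61280 was called higher in pif4 pif5 pif7 (1.04, limma adjusted p = 0.023) and in SOB3-D (0.85, adjusted p = 0.022). Its calls were lost with pseudocounts of 0.1 or 0.5 and without several single libraries. The count says nothing about single genes, and whether linked sequence changed these was not tested. With all libraries thinned to the shallowest, 3963 genes were called in SOB3-D against 4887 at full depth.

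Of the 10 splits of each set of 6 libraries, 1 (the real one) gave as many called genes, with 2475, 4887, 1171 and 6607 genes for sob3-6, SOB3-D and the triple mutant against Col-0 and for sob3-6 against SOB3-D, and 0, 0, 1 and 0 in the highest other split. Splits of 3 against 3 are too few for a share under 0.05. Of 100 splits of the libraries, 1 (the real one) gave as many genes in each overlap: 355 opposite in sob3-6 and SOB3-D (highest other 0), 294 opposite in sob3-6 and pif4 pif5 pif7 (0), 333 the same way in SOB3-D and pif4 pif5 pif7 (39), and 500 opposite between the AHL lines' contrast and pif4 pif5 pif7 (170). At most 2 of the 99 other splits called enough genes in both comparisons to share as many, and the median number called was 0, so this says nothing about whether genes are shared beyond chance. Independent lists would share 259 and 84.4 genes where 218 and 137 were opposite in sob3-6 and SOB3-D.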
